A study of Mus musculus with 8 samples.

How the data were processed

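RNA sequencing of mouse OT-I CD8+ T cells was analysed in 8 libraries. OT-I cells carry a transgenic T cell receptor for an ovalbumin peptide. Per the labels, the cells had been cultured for 72 hours with antigen-bearing dendritic cells (DC) of 1 subset, and the T cells that had divided were then sorted into lysis buffer. The DC partner given in the labels defined the groups. There were 3 libraries with migratory CD103+ DC (CD103 DC group), 3 with lymph node resident CD8a+ DC (CD8a DC group) and 2 with migratory CD11b+ DC (CD11b DC group, numbered 2 and 3). The labels do not say whether the libraries of a group came from separate cultures or animals. The p-values therefore measure the spread between these samples, which may be technical.

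The deposited table listed 43432 genes by Ensembl identifier, of which 759 had no symbol. Per the submitters' processing notes, STAR 2.4.2a, DESeq2 (version not given) and the genome build GRCm38 were used. The read counter, the annotation release and the strand setting are not given in the sources used here. Per the file headers, the authors deposited normalized counts per library, a signal in which each gene count is divided by 1 size factor per library. Per the file headers they also deposited variance-stabilized log2 values, and for each pair of groups a fold change (ratio), a log2 fold change, a p-value and an adjusted p-value. The deposited gene GC percent and gene coordinates came with the table. The coordinates printed here are those gene spans, 1-based, on GRCm38. The variance-stabilized values, whose lowest value was 8.57, and the deposited gene GC percent were not used in any test.

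The design fixed before the data were examined named edgeR quasi-likelihood with TMM scaling for raw counts, and limma-trend for a table without them. Because the table holds normalized counts, limma-trend (limma 3.58.1, R 4.3.3) on log2(normalized count + 1) was the test, for 18971 genes with a mean normalized count of at least 1. One fit held all 8 libraries with 3 group means and no block, with 5 residual degrees of freedom, and each pair of groups was a contrast. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes of its contrast. Fold changes are differences of mean log2(normalized count + 1). For low genes they can lie below or above the ratio of mean CPM. Each was oriented as the first group named over the second.

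Low values in each library were whole multiples of 1 step, so reads could be recovered. Of the values used to find the step, 100% came out whole within 0.1 of a read in each of the 8 libraries. The recovered totals were 16293042 to 21973391 reads per library. CPM values (the signal of a gene scaled to a common library total) were computed from the deposited normalized counts. They are given as mean ± SD over libraries, with n = 3, 3 and 2. Where a group had 0 reads, the fold was computed against a floor of 3 reads over the group and is a lower bound. Floors cover counting error only. Count tests on the recovered reads (edgeR 4.0.16 quasi-likelihood, DESeq2 1.42.0, limma-voom) were alternatives. With TMM scaling, edgeR called 254 genes between the CD103 DC and CD8a DC groups, 63 between the CD103 DC and CD11b DC groups and 365 between the CD8a DC and CD11b DC groups, of 14931 genes tested.

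Before the data were examined, 17 functional gene lists, a T cell identity list, 8 lists of other-cell markers and 2 lists on sample handling were written down. The functional lists were tested with camera in the same fit, with a preset inter-gene correlation of 0.01 and adjustment over the 17 lists of a contrast. Camera compares a list with all other genes tested. Members were also counted with p-values adjusted over the list alone. Other-cell lists were given as summed CPM, without a test of the list. Genes to be named were fixed by rule: in each direction up to 10 genes with the largest fold among those that passed, with a mean of at least 5 CPM in the higher group and no overlap between libraries. Predicted genes and receptor segments were passed over. The rule added up to 4 members per functional list with the smallest adjusted p, and always Ifng, Gzmb, Prf1, Il2, Il2ra, Tbx21, Eomes, Tcf7, Pdcd1, Itgae and Cd8a. Some genes that the rule named are not reported here. Other called list members are named as such.

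The steps were tested on simulated data drawn from the real means and library sizes. In the simulated CD103 DC against CD8a DC contrast (18214 genes), 33.7% of 95 genes changed 2-fold and 45.3% of 95 changed 4-fold were recovered, and 8 of 88 calls were false (9.09%). For the CD103 DC against CD11b DC contrast (18184 genes), 30.9% of 97 and 43.6% of 94 were recovered, with 6 of 83 calls false (7.23%). For the CD8a DC against CD11b DC contrast (18210 genes), 21.7% of 92 and 43.6% of 94 were recovered, with 10 of 74 calls false (13.5%). The false share thus lay above the nominal 5% in each simulated contrast. Among simulated genes with a mean normalized count of at least 50, recovery of 2-fold changes was 57.1%, 50.0% and 36.4% in this order. For 4-fold changes it was 86.0%, 78.8% and 75.9%. Of 20 unchanged lists per contrast, 0 were called. The simulated genes were drawn independently, so this result does not cover lists whose genes vary together.

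Alternatives fixed beforehand were other scalings, filters, pseudocounts and tests, a fit of only the groups compared, the replicate number as a block, a 1.2-fold threshold, each library left out in turn, camera with an estimated correlation, fry, and lists without other-cell genes. A transcript length and GC correction, TMM scaling of the limma fit, and leaving out libraries under a stricter filter or with edgeR were chosen after seeing the data. So was running edgeR with TMM on the recovered reads, although the design had named that test for raw counts. The lengths and GC contents used in that correction and in matching random lists were those of the longest transcript per gene in a GENCODE annotation of GRCm38, found for 99.1% of the genes tested. Of the listed genes, Cd244a, Rigi, Gbp5 and Gbp6 were not analysed here. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.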

Results

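OT-I CD8+ T cells that had divided during 72 hours with migratory CD103+, resident CD8a+ or migratory CD11b+ dendritic cells were profiled by RNA sequencing. Depth was 16293042 to 21973391 recovered reads per library. T cell identity transcripts summed to 10010 ± 40.0 CPM in the CD103 DC group, 9307 ± 618 CPM in the CD8a DC group and 10270 ± 905 CPM in the CD11b DC group (SD; n = 3, 3 and 2). Markers of DC summed to 459 ± 10.1, 210 ± 83.7 and 489 ± 119 CPM in the same order. Mitochondrially encoded transcripts took 6.69% to 7.72% of reads with CD103+ DC, 9.12% to 11.8% with CD8a+ DC and 7.02% to 7.20% with CD11b+ DC. Replicate 2 of the CD8a DC group stood apart on the first principal component (20.9% of variance), at 138 against -44.0 to 26.1 for the other 7 libraries. It also had the highest share of reads in its 20 most abundant genes, 16.3%. The CD8a DC libraries correlated little or no better with their own group (mean r 0.9457, 0.9317 and 0.9383) than with the other groups (0.9462, 0.9279 and 0.9361). For the CD103 DC libraries these values were 0.9634, 0.9658 and 0.9608 against 0.9436, 0.9486 and 0.9367. For the CD11b DC libraries they were 0.9697 and 0.9697 against 0.9446 and 0.9473.

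Among the remaining marker lists, macrophage and monocyte genes summed to 158 ± 4.77 CPM in the CD103 DC group, 107 ± 31.4 in the CD8a DC group and 142 ± 8.14 in the CD11b DC group. B cell genes summed to 1091 ± 63.4, 1152 ± 153 and 1206 ± 31.2 CPM, of which Ighm alone gave 975.4, 1088 and 1148 CPM. Genes of CD4 and regulatory T cells summed to 30.8 ± 1.91, 10.5 ± 3.03 and 11.5 ± 1.71 CPM. Neutrophil genes summed to 0.476 ± 0.213, 0.240 ± 0.238 and 0.495 ± 0.631 CPM, and natural killer cell genes to 5.24 ± 1.26, 3.19 ± 1.08 and 4.46 ± 2.18. Red blood cell genes summed to 2.38 ± 1.43, 2.11 ± 0.337 and 3.48 ± 0.0594 CPM and stromal and epithelial genes to 6.52 ± 6.56, 7.02 ± 2.27 and 4.73 ± 0.614. Immediate early and heat shock genes summed to 1641 ± 95.1, 1547 ± 189 and 1372 ± 3.58 CPM. Mitochondrially encoded transcripts of the list summed to 56630 ± 6128, 71940 ± 12500 and 55250 ± 3710 CPM.

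The first comparison asked how T cells primed by migratory CD103+ DC differed from those primed by resident CD8a+ DC. T cells from the CD103 DC group had higher levels of interferon response genes, of selectin ligand enzymes and of the chemokine receptor Ccr4, and lower levels of the gut homing receptors Itga4 and Ccr9. Of the interferon gamma and type I interferon genes 12 of 25 and 5 of 34 passed, and neither list was called with an estimated correlation (adjusted p = 0.113 and adjusted p = 0.137). Gcnt1 and Fut7, glycosyltransferases that build selectin ligands, stood at 22.1 ± 4.54 and 11.2 ± 1.95 CPM against 1.62 ± 1.38 and 1.14 ± 0.577 CPM. Itga4, the alpha 4 integrin, stood at 142 ± 8.34 against 489 ± 108 CPM, and Ccr9, the receptor for the gut chemokine CCL25, at 9.02 ± 3.45 against 79.1 ± 33.0 CPM. Iigp1, an interferon-inducible GTPase, was 11.1-fold higher (7.31-fold without replicate 2 of the CD8a DC group), at 32.8 ± 3.91 against 3.25 ± 1.84 CPM. Of the 18971 genes, 273 passed, 169 higher and 104 lower in the CD103 DC group.

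Of the 33 homing, adhesion and tissue residence genes, 6 rose and 5 fell with CD103+ DC, and 9 rose and 11 fell when adjusted over the list alone. Gcnt1 (ENSMUSG00000038843; chromosome 19, 17326141 to 17356667) had a log2 fold change of 3.97 (SE 0.60, adjusted p = 0.00569; 4.63 without replicate 2 of the CD8a DC group). Itga4 (ENSMUSG00000027009; chromosome 2, 79255426 to 79333123) fell by 1.82 on the log2 scale (SE 0.16, adjusted p = 0.000295). Ccr9 (ENSMUSG00000029530; chromosome 9, 123678439 to 123784330) fell by 3.14 (SE 0.36, adjusted p = 0.00127). Ccr4 rose from 7.64 ± 4.44 to 38.5 ± 2.38 CPM, Gpr55 from 62.4 ± 6.30 to 148 ± 30.7, Ly6a from 38.8 ± 10.4 to 108 ± 14.3, and Itgal, the integrin LFA-1 alpha chain, from 578 ± 39.7 to 851 ± 47.8. Cxcr4, Gpr15 and Selplg, the core protein of the P-selectin ligand, fell, with log2 fold changes of -1.63, -1.02 and -0.55. Camera did not call this list (adjusted p = 0.685). Its median and mean were above 0 while camera's direction was down.

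The interferon gamma response list was called higher (camera, adjusted p = 2.43e-18). Of its 25 measured genes 12 rose and 0 fell (16 and 0 adjusted over the list alone). Beside Iigp1 (ENSMUSG00000054072; chromosome 18, 60376029 to 60392627; log2 fold change 3.47, SE 0.41, adjusted p = 0.00156; 2.87 without replicate 2 of the CD8a DC group), Gbp4 rose 1.92-fold, Nlrc5, a transactivator of MHC class I genes, 1.72-fold, and Cd274, the inhibitory ligand PD-L1, 2.37-fold. Gbp4 overlaps Gbp9 on chromosome 5, and the guanylate binding protein genes resemble one another, so reads may be split between them. Of 34 type I interferon response genes 5 rose and 0 fell (23 and 0 adjusted over the list alone), and that list was also called higher (adjusted p = 2.40e-15). Isg15 rose 8.30-fold (4.51-fold without replicate 3 of the CD8a DC group), Slfn8 2.18-fold and Zbp1 2.16-fold. With an estimated correlation neither call held (adjusted p = 0.113 for the interferon gamma list and adjusted p = 0.137 for the type I list). Fry did not call the type I list either (adjusted p = 0.0522).

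**Figure D1:**
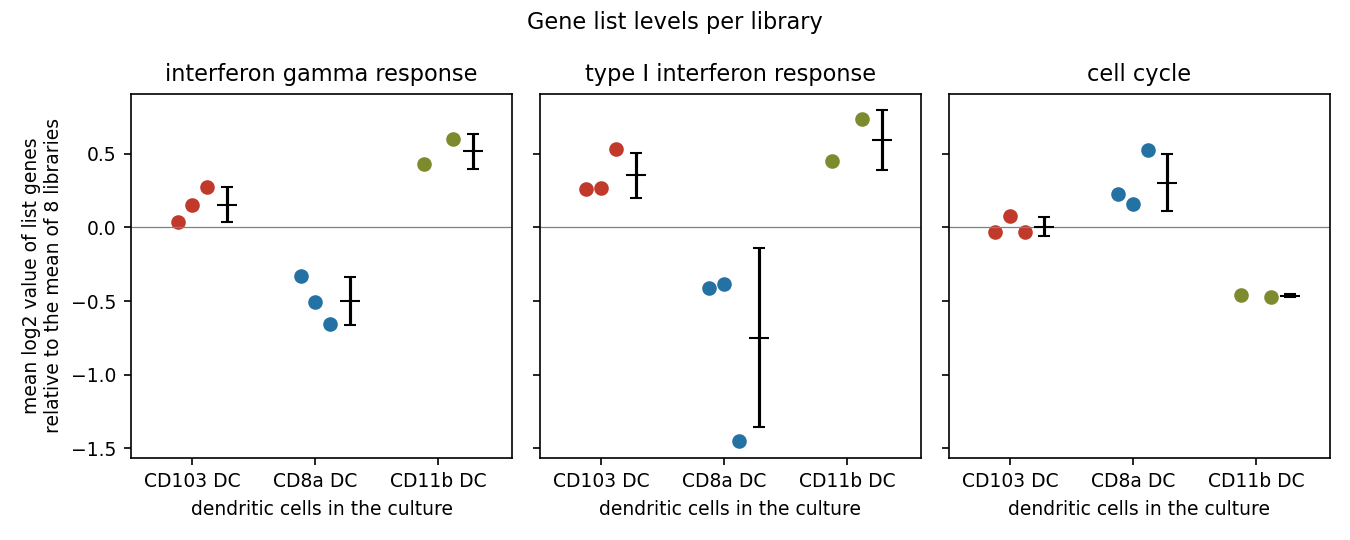
Mean log2 level of the genes of 3 lists (interferon gamma response, type I interferon response, cell cycle), relative to the mean of the 8 libraries, by the dendritic cells in the culture. Points are libraries and bars the mean ± SD. Both interferon lists lie below 0 in all 3 CD8a DC libraries, with replicate 3 at -1.45 for the type I list, and the cell cycle list lies at -0.46 and -0.47 in the CD11b DC libraries.

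The T cell receptor activation and cytokine lists were called higher with CD103+ DC, and the cell cycle, oxidative phosphorylation and ribosomal protein lists were called lower. Of 31 T cell receptor activation genes 2 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 5.66e-08, and adjusted p = 0.113 with an estimated correlation). Il2ra, the high-affinity interleukin 2 receptor chain, stood at 36.0 ± 13.7 against 10.4 ± 6.09 CPM (adjusted p = 0.0232), Cd69 at 37.0 ± 5.18 against 13.9 ± 1.12 CPM, and Dusp5 fell by 1.37 on the log2 scale. Of 19 measured cytokine genes 1 rose, Tnfsf8, by 2.77-fold (6 rose and 1 fell adjusted over the list alone; camera adjusted p = 1.18e-05, and adjusted p = 0.0719 with an estimated correlation). Of 42 cell cycle genes 5 fell and 0 rose (9 and 0 adjusted over the list alone), among them Ccnb2 and Birc5, with log2 fold changes of -0.70 and -0.55 (camera adjusted p = 1.41e-13, and adjusted p = 0.137 with an estimated correlation). Of 32 oxidative phosphorylation genes 2 fell, Cox6c and Cox4i1, with log2 fold changes of -0.65 and -0.56 (5 adjusted over the list alone; camera adjusted p = 1.50e-10, and adjusted p = 0.137 with an estimated correlation). Of 42 cytosolic ribosomal protein genes 2 fell, Rpl8 and Rps2, with log2 fold changes of -0.42 and -0.59 (3 adjusted over the list alone; camera adjusted p = 5.28e-10, and adjusted p = 0.183 with an estimated correlation). Fry did not call the cell cycle, oxidative phosphorylation and ribosomal protein lists (adjusted p = 0.0574, 0.0522 and 0.0574). Across 10700 genes the fold change rose with transcript length (Spearman 0.169; genes are not independent replicates), from a median of -0.15 under 1 kb to 0.14 over 8 kb.

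Of 20 inhibitory receptor and exhaustion regulator genes 3 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.00332, adjusted p = 0.139 with an estimated correlation, 0.0522 with fry, and adjusted p = 0.107 without replicate 1 of the CD8a DC group). Cish, a suppressor of cytokine signalling, rose 6.18-fold and Tox 2.01-fold, while Ctla4 fell by 0.69 on the log2 scale. In the lists that were not called, Gzmk, a granzyme, fell from 9.89 ± 8.45 to 0.138 ± 0.130 CPM (adjusted p = 0.00591). Its log2 fold change of -5.77 became -5.03 without replicate 3 of the CD103 DC group and -5.13 without replicate 1 of the CD8a DC group. By contrast, Klrk1, the activating receptor NKG2D, and Tnfsf10, the death ligand TRAIL, rose 2.84-fold and 2.04-fold. Bhlhe40 and Rora rose 3.37-fold and 2.30-fold, while Ikzf3 and Klf2 fell, with log2 fold changes of -0.68 and -1.11. Rara and Cdkn1a rose 2.06-fold and 2.97-fold, and Il6ra and Pim2 rose 2.81-fold and 1.65-fold. The glycolysis, sterol and amino acid lists had 0 genes that passed and were not called. The cytotoxic, naive and memory, transcription factor, TGF-beta and retinoic acid, and apoptosis lists were not called either. Some of these were called when 1 library was left out: the sterol list without replicate 1 of the CD103 DC group or replicate 3 of the CD8a DC group (adjusted p = 0.00896 and 0.00163), the naive and memory list and the TGF-beta and retinoic acid list without replicate 3 of the CD8a DC group (0.00282 and 0.0448), and the apoptosis list without its replicate 2 (0.0430). Median, mean and test also differed in sign for the naive and memory, glycolysis, amino acid, and TGF-beta and retinoic acid lists.

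Other genes with the largest folds were H2-M2 (10.2 ± 2.09 against 0.614 ± 1.06 CPM), Cd22 (5.40 ± 3.57 against 0.0348 ± 0.0602), Penk (5.54 ± 0.852 against 0.111 ± 0.107), Npr1 (6.36 ± 0.903 against 0.186 ± 0.122), Flrt3, Ankrd33b and Sdc4, all higher with CD103+ DC. Nid1, Car2, Hic1, Plac8, Slco4a1 and Tubb2a were among the genes with the largest falls, with log2 fold changes of -5.18, -2.98, -2.6, -2.06, -1.99 and -1.65. Nid1 stood at 0.492, 12.8 and 1.81 CPM in the CD8a DC libraries against 0.0176 ± 0.0306 CPM, and its log2 fold change was -3.93 without replicate 2 of the CD8a DC group and -6.24 without replicate 1. H2-M2, at 5.83 with all libraries, had 7.56, 4.97 and 4.97 without replicates 1, 2 and 3 of the CD8a DC group. Penk, at 5.33, had 4.66 without replicate 2 of that group, and Flrt3, at 4.14, had 5.47 and 3.07 without its replicates 2 and 3. Without replicate 1 of the CD103 DC group Cd22, at 5.82, had 6.55 and Car2 had -3.74. The DC marker list moved with these genes: 5 of its 20 measured members rose and 0 fell (8 and 1 adjusted over the list alone), with H2-Aa at 21.2 ± 5.63 against 3.84 ± 0.563 CPM, Cd74 at 52.4 ± 5.12 against 17.8 ± 15.1 CPM (log2 fold change 1.81, and 2.47 without replicate 2 of the CD8a DC group) and Ccl22 at 152 ± 14.6 against 60.0 ± 27.3 CPM. Of the 4 CD4 and regulatory T cell markers 1 rose, Zbtb7b (adjusted p = 0.0282; 3 rose adjusted over the list alone), and the list summed to 30.8 ± 1.91 against 10.5 ± 3.03 CPM. The count of 273 fell to 0 by limma-trend when any library of the CD103 DC or CD11b DC group was left out, and to 4, 74 and 253 without replicates 1, 2 and 3 of the CD8a DC group. These fits had 1895 to 2746 genes at an unadjusted p under 0.05 (2502 with all libraries) and 60 to 479 genes called by edgeR. Scaling by library size gave 210 higher and 74 lower, and the length and GC correction 121 higher and 191 lower.

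**Figure D2:**
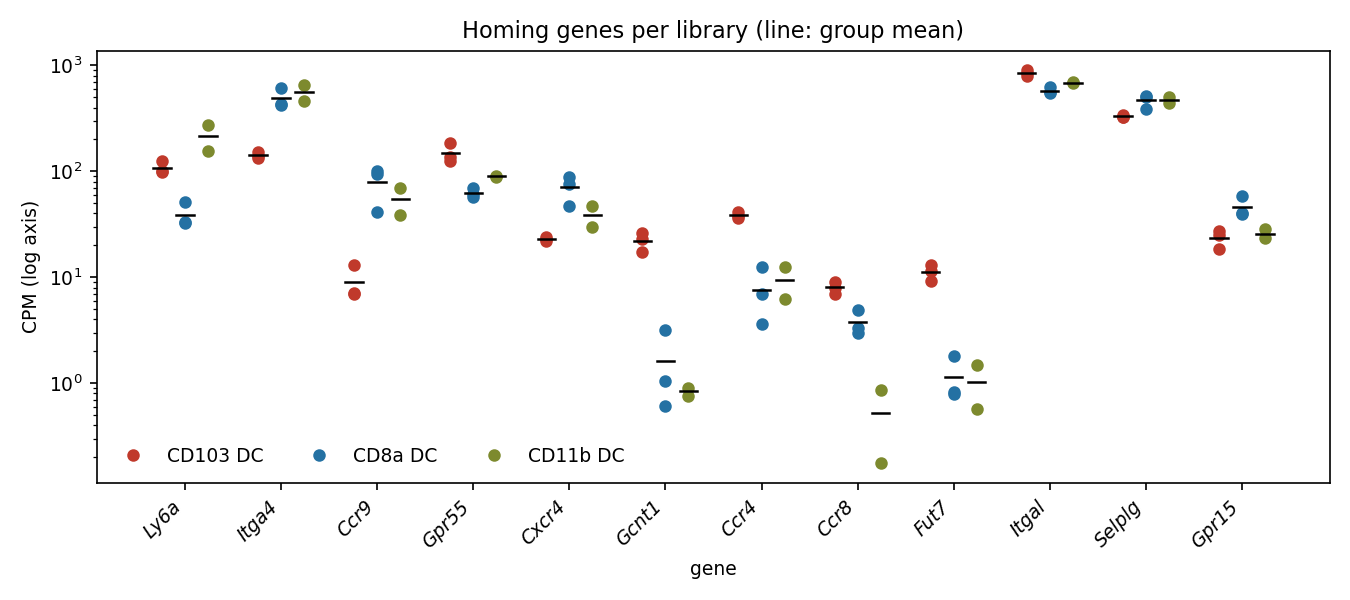
CPM of 12 homing genes (log axis) in each library of the 3 groups. Points are libraries and lines are group means. Gcnt1 has means of 22.1, 1.62 and 0.836 CPM in the CD103, CD8a and CD11b DC groups, and Itga4 means of 142, 489 and 558 CPM.

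The second comparison set the migratory subsets against each other. T cells from the CD103 DC group again had more Gcnt1 and Fut7 and more Ccr8, a chemokine receptor of skin homing T cells, and less Itga4, Ccr9 and Gzmb, a cytotoxic granule protease, than those from the CD11b DC group. Gcnt1 stood at 22.1 ± 4.54 against 0.836 ± 0.1004 CPM and Ccr8 at 8.02 ± 1.04 against 0.517 ± 0.482 CPM (n = 3 and 2). Gzmb stood at 12.9 ± 4.66 against 66.0 ± 14.4 CPM, and S100a4, a calcium-binding protein of effector and memory cells, at 2.23 ± 0.657 against 25.3 ± 5.77 CPM. Of the 18971 genes, 63 passed, 25 higher and 38 lower in the CD103 DC group.

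Of the 33 homing genes 3 rose and 3 fell (7 and 11 adjusted over the list alone). Gcnt1 had a log2 fold change of 4.61 (SE 0.67, adjusted p = 0.0120), Ccr8 (ENSMUSG00000042262; chromosome 9, 120092114 to 120094906) of 4.13 (SE 0.66, adjusted p = 0.0146) and Fut7 (ENSMUSG00000036587; chromosome 2, 25423267 to 25426374) of 3.501 (SE 0.66, adjusted p = 0.0425). Without replicates 2 and 3 of the CD11b DC group Ccr8 had 5.12 and 3.13 and Fut7 had 2.87 and 4.14. Itga4 fell by 1.96 (SE 0.17, adjusted p = 0.000475) and Ccr9 fell by 2.59 (SE 0.40, adjusted p = 0.0129) on the log2 scale. Itgb7, the integrin chain that pairs with alpha 4, fell by 0.71 (adjusted p = 0.0488). The list was called lower (camera adjusted p = 0.0322), but not with an estimated correlation (adjusted p = 0.255) or without replicate 2 of the CD103 DC group (adjusted p = 0.114), replicates 1, 2 or 3 of the CD8a DC group (0.0574, 0.0750 and 0.0531) or replicates 2 or 3 of the CD11b DC group (0.143 and 0.145). Of 20 TGF-beta and retinoic acid response genes 2 fell, Itga4 and Ccr9 (1 rose and 3 fell adjusted over the list alone), and the list was called lower at an adjusted p = 0.0338, but at an adjusted p = 0.419 with an estimated correlation. Without single libraries the adjusted p of that list was 0.0778 and 0.0887 for replicates 1 and 2 of the CD103 DC group, 0.0609, 0.0923 and 0.105 for replicates 1, 2 and 3 of the CD8a DC group, and 0.0596 and 0.167 for replicates 2 and 3 of the CD11b DC group.

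Cell cycle genes were higher with CD103+ DC than with CD11b+ DC. Of 42 genes 3 rose, Foxm1 by 1.70-fold, Top2a by 1.48-fold and Mki67 by 1.39-fold, and 29 rose adjusted over the list alone (camera adjusted p = 1.33e-27, and adjusted p = 0.107 with an estimated correlation). The interferon gamma response list was called lower with CD103+ DC (adjusted p = 5.56e-07, and adjusted p = 0.289 with an estimated correlation), with 0 of 25 genes passing and 2 that fell adjusted over the list alone. Of 34 type I interferon response genes 0 passed and 1 fell adjusted over the list alone (camera adjusted p = 0.00350, adjusted p = 0.419 with an estimated correlation, 0.0693 without replicate 2 of the CD103 DC group and 0.301 without replicate 3 of the CD11b DC group). The cytotoxic list was called lower (adjusted p = 0.000246, adjusted p = 0.107 with an estimated correlation, and 0.0508 without replicate 3 of the CD11b DC group), and of its 21 genes 1 fell, Gzmb (5 adjusted over the list alone). Gzmb (ENSMUSG00000015437; chromosome 14, 56258838 to 56262260) fell by 2.4 on the log2 scale (SE 0.42, adjusted p = 0.0253). Of 25 naive and memory genes 1 fell, Klf3, by 1.11 on the log2 scale (3 adjusted over the list alone; camera adjusted p = 0.00115, and adjusted p = 0.419 with an estimated correlation).

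Further lists were called with few or 0 single genes behind them, and each was lost with an estimated correlation (adjusted p = 0.419 for each of the 5). Fry called 0 of the 17 lists in this comparison, with adjusted p = 0.05102 for cell cycle, 0.0692 for cytotoxic and 0.153 for interferon gamma genes. The oxidative phosphorylation list was higher and the ribosomal protein list lower (adjusted p = 0.00350 for both), with 0 genes passing in either, and 0 adjusted over the list alone. Their medians lay at percentiles 83.7 and 0.41 of 10000 random lists matched on length, GC and expression. Their adjusted p was 0.0930 without replicate 2 of the CD103 DC group for the former and 0.534 without replicate 3 of the CD11b DC group for the latter. The sterol list was higher (adjusted p = 0.00350, and 0.0693 without replicate 2 of the CD103 DC group), with 0 genes passing and 0 adjusted over the list alone. The T cell receptor activation list was higher (adjusted p = 0.00888, 0.0693 without replicate 2 of the CD103 DC group and 0.167 without replicate 3 of the CD11b DC group), with 0 genes passing and 1 that rose adjusted over the list alone. The amino acid list was higher (adjusted p = 0.0322), although Slc7a11, a cystine transporter and the 1 member that passed, fell by 3.40 on the log2 scale (1 rose and 1 fell adjusted over the list alone). Its adjusted p was 0.0778 and 0.114 without replicates 1 and 2 of the CD103 DC group, 0.376 without replicate 3 of the CD11b DC group and 0.0591 with the length and GC correction. The cytokine, inhibitory receptor, transcription factor, glycolysis and apoptosis lists were not called, and the transcription factor list had a median above 0 and a mean below 0. The cytokine list was called without replicate 2 of the CD8a DC group (adjusted p = 0.0301). In the transcription factor list Ikzf3 fell by 0.78 on the log2 scale.

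The remaining genes with the largest folds were Maged1, Lmna, H2-Aa, Wnt10a, Hemgn, Sema6d and Acsl3, which rose 11.3-fold, 8.26-fold, 7.23-fold, 6.83-fold, 5.65-fold, 5.57-fold and 3.42-fold. Lmna was 16.2-fold and 4.21-fold higher without replicates 2 and 3 of the CD11b DC group. Hic1, Art2b, Plac8, Gimap7 and Prrt1 fell, with log2 fold changes of -2.99, -2.31, -2.28, -1.83 and -1.78. Among DC markers 1 rose, H2-Aa, and 1 fell, Sirpa, a receptor of CD11b+ DC, listed at 0.0347 ± 0.0601 against 2.78 ± 1.30 CPM (2 rose and 3 fell adjusted over the list alone). The count of 63 fell to 0 by limma-trend without any of the CD103 DC or CD11b DC libraries, and was 1, 4 and 104 without replicates 1, 2 and 3 of the CD8a DC group. In these fits 1286 to 2171 genes lay at an unadjusted p under 0.05 (1769 with all libraries) and edgeR called 1 to 228.

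**Figure D3:**
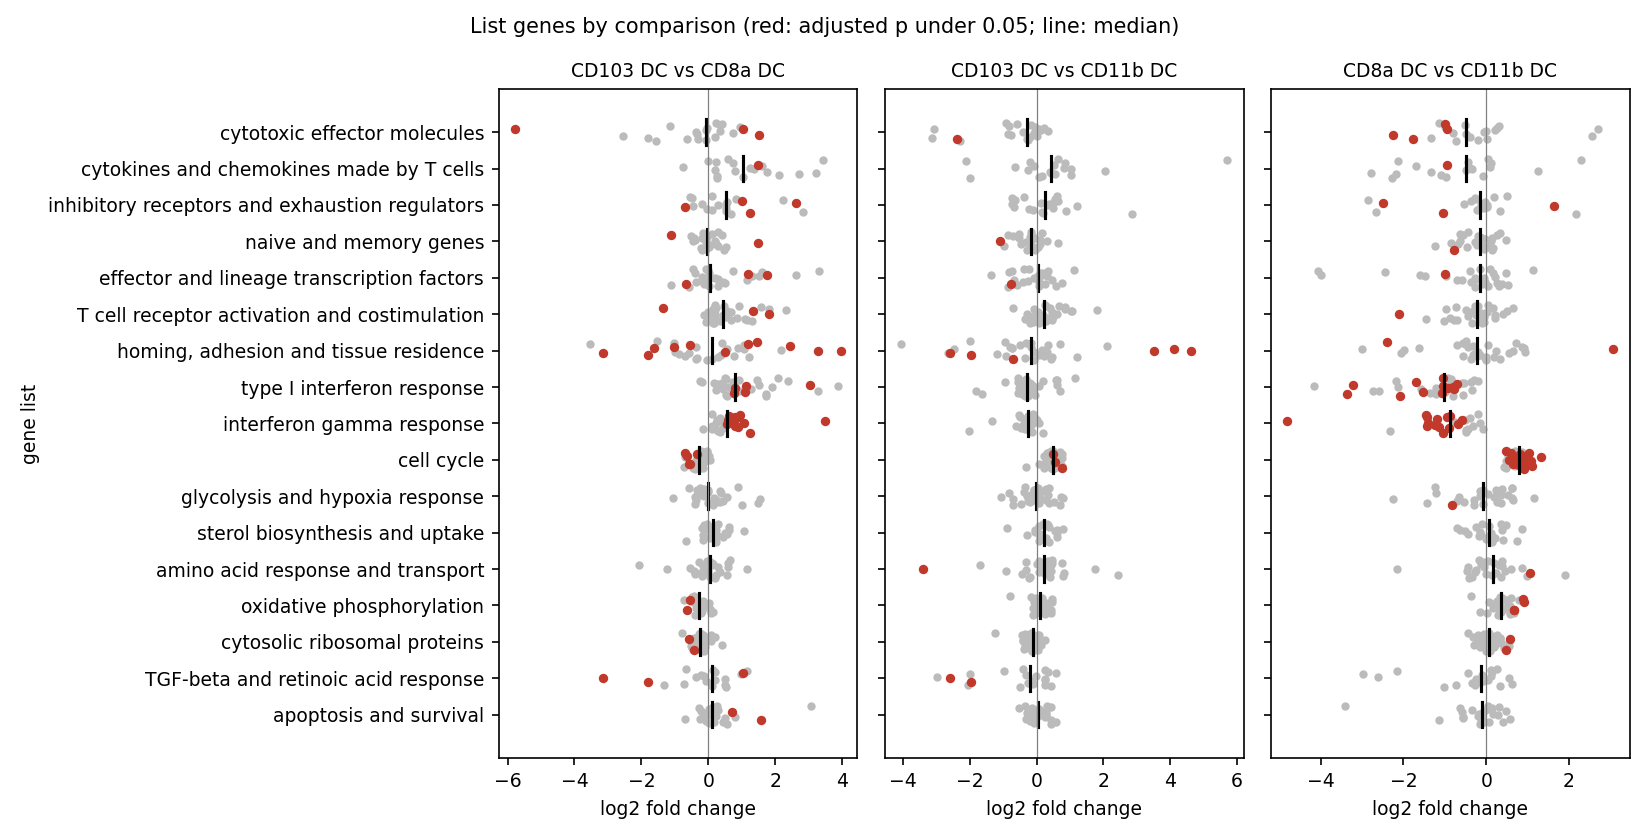
Log2 fold change of each gene of the functional lists in the 3 comparisons. Red points passed an adjusted p under 0.05 over all genes, grey points did not, and lines are list medians. In the CD8a DC against CD11b DC panel the cell cycle list has a median of 0.79 and the interferon gamma list a median of -0.88.

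The third comparison set resident CD8a+ DC against migratory CD11b+ DC. T cells from the CD8a DC group had more of 24 of 42 cell cycle genes and less of 14 of 25 interferon gamma response genes, 12 of 34 type I interferon response genes, 4 of 21 cytotoxic effector genes and Il2ra. With an estimated correlation these lists were not called (adjusted p = 0.0517, 0.0517, 0.113 and 0.113 in that order), and the cytotoxic list had an adjusted p = 0.142 without replicate 3 of the CD11b DC group. Mki67, a marker of cycling cells, stood at 3970 ± 380 against 2311 ± 70.9 CPM (n = 3 and 2). Iigp1 stood at 3.25 ± 1.84 against 83.2 ± 22.9 CPM, and Ly6a, the interferon-responsive surface protein Sca-1, at 38.8 ± 10.4 against 215 ± 83.7 CPM. Of the 18971 genes, 374 passed, 203 higher and 171 lower in the CD8a DC group.

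Of the 42 cell cycle genes 24 rose and 0 fell (41 and 0 adjusted over the list alone; camera adjusted p = 7.80e-47). Mki67 (ENSMUSG00000031004; chromosome 7, 135689784 to 135716361) had a log2 fold change of 0.83 (SE 0.09, adjusted p = 0.000473), Top2a, a DNA topoisomerase, of 0.71 (SE 0.09, adjusted p = 0.00185) and Foxm1, a mitotic transcription factor, of 0.91 (SE 0.14, adjusted p = 0.00447). With an estimated correlation the list had an adjusted p = 0.0517. Of 32 oxidative phosphorylation genes 4 rose (14 adjusted over the list alone; camera adjusted p = 2.65e-15, and adjusted p = 0.113 with an estimated correlation), with Ndufa4 1.89-fold and Ndufv1 1.85-fold higher. The share of mitochondrially encoded reads was also higher in the CD8a DC group, and mt-Nd1 rose. Of 42 ribosomal protein genes 2 rose, Rpl8 1.38-fold and Rps2 1.48-fold (3 adjusted over the list alone; camera adjusted p = 0.00986, adjusted p = 0.490 with an estimated correlation, 0.295 without replicate 2 of the CD8a DC group 0.319 without replicate 2 of the CD11b DC group and 0.338 with fry). The ribosomal median of 0.06 lay below the 0.17 of random lists matched on length, GC and expression, at percentile 5.15, and that of the oxidative phosphorylation list, 0.36, above their 0.13. Fold changes fell with transcript length across 10700 genes (Spearman -0.150), from a median of 0.08 under 1 kb to -0.19 over 8 kb.

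Of 25 interferon gamma response genes 14 fell and 0 rose (19 and 0 adjusted over the list alone; camera adjusted p = 3.15e-27, and adjusted p = 0.0517 with an estimated correlation). Iigp1 fell by 4.80 on the log2 scale (SE 0.46, adjusted p = 0.000215), and had a log2 fold change of -4.20 without replicate 2 of the CD8a DC group. Igtp and Gbp4 fell, with log2 fold changes of -1.42 (SE 0.16, adjusted p = 0.000473) and -1.46 (SE 0.14, adjusted p = 0.000202). Of 34 type I interferon response genes 12 fell and 0 rose (21 and 0 adjusted over the list alone; camera adjusted p = 1.25e-19, and adjusted p = 0.113 with an estimated correlation). Rsad2 and Isg15, antiviral effectors, fell, with log2 fold changes of -3.36 and -3.21 (Isg15 -2.33 without replicate 3 of the CD8a DC group). Those of Xaf1, Zbp1 and Slfn8 were -1.71, -1.53 and -1.04.

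Of 21 cytotoxic effector genes 4 fell, namely Gzmb, Klrk1, Tnfsf10 and Cst7, which had 66.0 ± 14.4, 94.8 ± 6.26, 64.4 ± 6.97 and 57.9 ± 18.5 CPM in the CD11b DC group and 21.3 ± 14.3, 20.2 ± 7.76, 32.7 ± 7.59 and 27.4 ± 2.81 CPM in the CD8a DC group (5 adjusted over the list alone; camera adjusted p = 0.00587, adjusted p = 0.113 with an estimated correlation, and 0.142 without replicate 3 of the CD11b DC group). Il2ra (ENSMUSG00000026770; chromosome 2, 11642807 to 11693193) stood at 10.4 ± 6.09 against 41.9 ± 0.811 CPM (log2 fold change -2.10, SE 0.39, adjusted p = 0.0128) and was the 1 of 31 T cell receptor activation genes that passed (4 fell adjusted over the list alone). That list was called lower at an adjusted p = 0.0220, with adjusted p = 0.345 with an estimated correlation, 0.125 and 0.0941 without replicates 1 and 2 of the CD8a DC group, 0.122 without replicate 2 of the CD11b DC group, 0.213 with fry and 0.0502 with the length and GC correction. Of 19 cytokine genes Tnfsf8 fell, by 0.96 on the log2 scale (1 adjusted over the list alone; camera adjusted p = 0.0244, adjusted p = 0.115 with an estimated correlation, 0.0740 without replicate 1 of the CD8a DC group and 0.0850 without replicate 2 of the CD11b DC group). In lists that were not called, Pdcd1, the inhibitory receptor PD-1, rose from 3.79 ± 0.0457 to 11.7 ± 2.03 CPM (log2 fold change 1.64, SE 0.37, adjusted p = 0.0329), and Cish and Cd274 fell, with log2 fold changes of -2.49 and -1.06. Psat1, a serine synthesis enzyme, rose 2.08-fold and Ccr8 8.41-fold (16.8-fold and 4.22-fold without replicates 2 and 3 of the CD11b DC group). Slc2a3, a glucose transporter, Il7r and Rora fell from 214 ± 28.2, 211 ± 26.2 and 74.3 ± 3.03 CPM to 116 ± 14.4, 120 ± 24.3 and 36.1 ± 6.47 CPM. The inhibitory receptor, naive and memory, transcription factor, homing, glycolysis, sterol, amino acid, TGF-beta and retinoic acid, and apoptosis lists were not called, and the glycolysis list had a median and mean below 0 where camera's direction was up. Without replicate 2 of the CD8a DC group the naive and memory, amino acid, and TGF-beta and retinoic acid lists were called (adjusted p = 0.00354, 0.0160 and 0.0399). The amino acid list was also called without replicate 2 of the CD11b DC group (0.0385) and the inhibitory receptor list without replicate 3 of the CD8a DC group (0.0268).

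The largest falls outside these lists were in Serpinb9b, a serine protease inhibitor of a gene family whose members may share reads, which had 0 reads in the CD8a DC group and 5.09 ± 0.0322 CPM in the CD11b DC group, at least 96.9-fold lower. Ccl17, H2-M2, S100a4, Nrp2, Ankrd33b and Vdr, the vitamin D receptor, fell, with log2 fold changes of -5.80, -5.31, -3.51, -2.99, -2.90 and -2.89. Maged1, Serpine2, Slco4a1, Cd24a, Zfp473, Gucy2e, Gch1, Lsm11 and Capg rose 6.11-fold, 4.53-fold, 4.12-fold, 3.76-fold, 3.51-fold, 3.45-fold, 3.36-fold, 3.06-fold and 3.03-fold. Without replicates 2 and 3 of the CD11b DC group Slco4a1 was 2.70-fold and 6.31-fold and Gucy2e 5.58-fold and 2.14-fold higher, and Ccl17 had log2 fold changes of -5.20 and -6.39. H2-M2 had -7.03, -4.44 and -4.44 without replicates 1, 2 and 3 of the CD8a DC group. Of 20 DC markers 3 fell, Ccl22, Ccl17 and Sirpa, with log2 fold changes of -2.20, -5.80 and -5.65 (1 rose and 5 fell adjusted over the list alone). The count of 374 became 42, 68 and 105 without replicates 1, 2 and 3 of the CD103 DC group, 58, 223 and 202 without those of the CD8a DC group, and 0 by limma-trend without either CD11b DC library. In these fits 1773 to 2868 genes lay at an unadjusted p under 0.05 (2577 with all libraries) and edgeR called 40 to 576. Scaling by library size gave 166 higher and 215 lower, and the length and GC correction 290 higher and 133 lower.

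Among the genes named whatever their outcome, Ifng stood at 2.76 ± 0.108 CPM in the CD103 DC group, 0.642 ± 1.01 CPM in the CD8a DC group and 0 in the CD11b DC group, and did not pass in any comparison (adjusted p = 0.201 against the CD8a DC group and 0.0909 against the CD11b DC group, at least 34.9-fold; adjusted p = 0.482 between the latter groups). Prf1, Il2, Tbx21, Eomes, Tcf7, Itgae and Cd8a did not pass in any of the 3 comparisons either. Prf1 stood at 5.81 ± 0.829, 6.13 ± 2.32 and 6.09 ± 4.35 CPM in the CD103, CD8a and CD11b DC groups, Tbx21 at 13.8 ± 4.96, 19.3 ± 4.71 and 23.7 ± 1.96, and Eomes at 74.8 ± 14.7, 93.7 ± 6.22 and 69.3 ± 5.96. Itgae, which encodes CD103 itself, stood at 411 ± 32.6, 402 ± 203 and 302 ± 25.4 CPM.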

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

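Length and GC correction, TMM scaling, and leaving out libraries under the stricter filter or with edgeR were tests chosen only after results were seen. The same holds for running edgeR with TMM on the recovered reads, although the design had named that test for raw counts. For 273, 63 and 374 genes changed (CD103 DC against CD8a DC, CD103 DC against CD11b DC, CD8a DC against CD11b DC), pseudocounts of 0.1 and 5, library size or TMM scaling, edgeR with either scaling, voom and the length and GC correction gave counts within 1.5 times. DESeq2 gave 843, 364 and 948. The authors' deposited table listed 743, 339 and 911, of which 242, 58 and 341 were also called here, in the same direction. The authors gave no adjusted p for some genes reported here as changed, so those calls cannot be compared. Between the CD103 DC and CD8a DC groups these included Iigp1, Isg15, Il2ra, Zbp1, Bhlhe40, H2-M2, Flrt3 and Gzmk. Between the CD103 DC and CD11b DC groups they included Gzmb and S100a4. Between the CD8a DC and CD11b DC groups they included Iigp1, Isg15, Il2ra, Gzmb, Ccl17, Vdr and Serpinb9b. Fits of only the groups compared gave 0, 0 and 0 by limma-trend, with fewer residual degrees of freedom and 2144, 2479 and 2300 genes at an unadjusted p under 0.05; no other tool was run on them. Against a 1.2-fold change 68, 21 and 95 genes passed. No filter gave 159 in the first comparison and the stricter filter 119 in the second, and the cause was not tested.

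Leaving out 1 library also gave a wide range of counts. Under the filter as reported and the added fits together, the lowest and highest counts were 0 and 683, 0 and 377, and 0 and 878. A CD11b DC library left alone is assumed to vary like the other groups. Under the filter as reported the prior degrees of freedom fell from 8.88 to between 2.4 and 4.98, with 27 to 120 genes of zero variance. Under the stricter filter, with 0 such genes, they were 9.40 to 13.5 and the counts were 108 to 683, 6 to 377 and 105 to 878, and with edgeR 60 to 479, 1 to 228 and 40 to 576. The CD103 DC against CD11b DC count thus ranged from below to above 63 in each of these 3 kinds of fit (0 to 104 under the filter as reported).

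Lists called numbered 8, 12 and 8. With an estimated correlation 0, 0 and 0 were called, and fry, which asks whether a list moves 1 way on balance, called 3, 0 and 6. Leaving out 1 library gave 7 to 11, 5 to 12 and 6 to 9 lists. Of the genes named in the report that passed (53, 25 and 51), 49, 25 and 49 passed with edgeR and TMM and 51, 25 and 50 with DESeq2. With the replicate number as a block 40, 20 and 39 of them passed, and against a 1.2-fold change 24, 15 and 21. In fits of only the groups compared 0, 0 and 0 passed.

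The labels do not say whether same-numbered libraries were made together. Same-numbered libraries of the CD103 DC and CD8a DC groups had deviations correlated at -0.0788 to 0.0302. Those of the CD11b DC group with either other group correlated at 0.00234 to 0.0164. Not every library correlated best with its own number. With so few libraries these values cannot show whether the numbers pair the samples. With the number as a block, 181, 49 and 279 genes and 8, 11 and 9 lists were called. The amino acid list had an adjusted p = 0.0506 (CD103 DC against CD11b DC) and, for CD8a DC against CD11b DC, the T cell receptor activation list 0.0972, the naive and memory list 0.0214 and the transcription factor list 0.0299.

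At 16293042 to 21973391 reads per library, Il2, at 0.0887 to 0.485 CPM on average, rests on few reads.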

Other observations

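The gene families in the next paragraphs, the comparison of interferon genes with DC transcripts and that of H2-Aa with other class II genes are tests chosen only after results were seen. Several GTPase genes of the Gimap family were lower in the CD103 and CD8a DC groups than with CD11b+ DC. Gimap4 stood at 804 ± 63.1, 1009 ± 68.5 and 1573 ± 90.2 CPM in the CD103, CD8a and CD11b DC groups. Of 9 measured genes, the antisense Gimap1os included, 4 fell with CD103+ DC (Gimap3, Gimap4, Gimap6 and Gimap7) and 3 with CD8a+ DC (Gimap4, Gimap6 and Gimap7), each against CD11b+ DC. The family medians were -0.56 and -0.50. Gimap1 stood at 303 ± 17.4 CPM in the CD103 DC group and 308 ± 5.51 CPM in the CD11b DC group (adjusted p = 0.978), and Gimap9 at 50.6 ± 3.24 CPM in the CD8a DC group against 47.9 ± 1.96 CPM (adjusted p = 0.854). The genes have related sequences, so their values are uncertain where reads were split between members.

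Several receptor genes were higher with CD103+ DC than with CD8a+ DC. Il18r1 and Il18rap, the chains of the interleukin 18 receptor, stood at 151 ± 27.8 and 58.2 ± 3.30 CPM against 41.2 ± 29.8 and 20.01 ± 4.36 CPM with CD8a+ DC (limma adjusted p = 0.0210 and 0.0133). Against CD11b+ DC they did not pass (0.348 and 0.0521). The retinoid receptor gene Rxra stood at 59.9 ± 12.8 CPM against 24.2 ± 5.15 and 23.2 ± 1.33 CPM (adjusted p = 0.0134 and 0.0348). Of 4 retinoid receptor genes measured, 2 rose against CD8a+ DC (Rxra and Rara) and 1 against CD11b+ DC, where Rara, Rxrb and Rarg did not pass (0.254, 0.975 and 0.837). Ighd stood at 98.1 ± 5.35, 46.5 ± 9.29 and 39.3 ± 1.61 CPM, and Zfp318, a factor needed for IgD transcripts in B cells, at 129 ± 7.49, 58.3 ± 8.93 and 58.9 ± 6.35 CPM. Both rose with CD103+ DC against either group (adjusted p = 0.00911 and 0.00405, then 0.0120 and 0.0127), while Ighm did not pass.

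The interferon lists were called lower with CD8a+ DC against either other group, but not with an estimated correlation (adjusted p = 0.113 for type I and 0.0517 for interferon gamma against CD11b+ DC, 0.137 and 0.113 against CD103+ DC). Fry did not call the type I list against CD103+ DC (0.0522). It called the interferon gamma list there (0.0172), and the type I and interferon gamma lists against CD11b+ DC (0.0298 and 0.00359). Of the median falls of the type I and interferon gamma lists against CD11b+ DC, 89.5% and 91.7% were kept after the length and GC correction. That correction also re-centred each library and moved other medians, for example cell cycle from 0.79 to 0.84. The medians of -1.02 and -0.88 lay below those of 10000 random lists matched on length, GC and expression, whose medians were -0.03 and 0.07. Random lists do not allow for list genes that vary together. The distance from their medians still argues against a length trend as the whole source. For RNA of DC, the 26 called interferon genes differed by a summed 4199 CPM. This was 593 times the 7.09 CPM of H2-Ab1 and H2-Eb1, abundant DC transcripts, in the CD11b DC group, where Cd74 stood at 22.1 CPM. The 26 genes were picked because they differed in this comparison, and other DC markers stood higher than H2-Ab1 and H2-Eb1. The DC marker list summed to 489 ± 119 CPM with CD11b+ DC against 210 ± 83.7 CPM with CD8a+ DC. Within it Ccl22 stood at 268 ± 66.6 against 60.0 ± 27.3 CPM. The ratio thus depends on the markers taken and cannot decide the question, so DC RNA stays open. The DC subset and other differences between the cultures stay open and were not tested. Replicate 3 of the CD8a DC group, at -1.45 for the type I list against -0.41 and -0.38 for the others, was the lowest, and both lists were still called lower against CD11b+ DC when any 1 of the 8 libraries was left out.

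The oxidative phosphorylation and ribosomal protein lists were called higher with CD8a+ DC than with CD103+ DC (2 of 32 and 2 of 42 genes passed), but not with an estimated correlation (adjusted p = 0.137 and 0.183) or fry (0.0522 and 0.0574). Their median log2 fold changes of -0.26 and -0.24 lay at percentiles 0.38 and 1.28 of matched random lists, whose medians were -0.13 and -0.13. Random lists do not allow for list genes that vary together, so these percentiles cannot decide whether a length trend was the whole source. After the length and GC correction the medians were -0.35 and -0.25. That correction also re-centred each library and lowered the medians of most lists in this comparison, for example cell cycle from -0.28 to -0.39. The corrected medians therefore cannot decide the question either. An altered metabolic state of the cells and a difference in RNA quality, which the higher mitochondrial share of the CD8a DC group also leaves possible, stay open and were not tested.

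Of 20 DC markers 5 rose and 0 fell in the CD103 DC group against the CD8a DC group, although divided T cells had been sorted, and H2-DMa, Clec9a and Itgam had log2 fold changes of -0.80, -2.75 and -1.09 without passing. If DC RNA were the source, class II genes would rise together with H2-Aa, which had a log2 fold change of 2.37. H2-Ab1 had -0.34, a gap of 3.90 standard errors, which argues against it, whereas Cd74 rose with 1.81 (gap 1.02; 2.47 without replicate 2 of the CD8a DC group), H2-Eb1 had 3.74 (gap -1.37, adjusted p = 0.0682), and Flt3 and Cd83 rose with 1.78 and 1.39. Values thus go both ways, and DC RNA and expression by the T cells cannot be told apart. Genes typical of single DC subsets did not all follow the groups: Itgam, typical of CD11b+ DC, stood at 0.312, 4.15 and 0.197 CPM in the CD103 DC libraries, 0.492, 8.06 and 0.689 in the CD8a DC libraries and 2.82 and 0.765 in the CD11b DC libraries, while Sirpa stood at 1.86 and 3.70 in the last and at most 0.104 in the others, and of genes typical of CD8a+ and CD103+ DC, Clec9a stood at 0.206, 0.307 and 0, then 1.84, 4.51 and 0.104, then 0 and 0, and Xcr1 at 0.471, 1.49 and 2.48, then 0.613, 0 and 0.423, then 0.480 and 1.18.

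For the 273 genes changed between the CD103 DC and CD8a DC groups, the 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split (1 of the 10) gave 273 genes by limma-trend in the fit that also held the CD11b DC libraries, and the highest of the other splits 0. A limma-trend fit of only the 6 libraries gave 0 genes for the real split. Each other split mixes libraries of both groups, which puts any group difference into its spread, so few calls would be found there in any case.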
